A study of Mus musculus with 2 samples.

How the data were processed

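H3K27me3, trimethylation of lysine 27 of histone H3, is the mark left by Polycomb repressive complex 2 and is found at silent developmental genes. It was measured by ChIP-seq in the embryonic facial prominence of B6NCrl mouse embryos at day 10.5, with male and female embryos pooled, per the labels. The 2 samples formed 1 group. Replicate 1 pooled tissue of 69 embryos and had 2 technical replicates; replicate 2 pooled tissue of 51 embryos and had 3. The labels call them biological replicates and give a size range of 300 to 500 bp for both libraries.

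Per the file headers and the notes deposited with the lists, the authors made 4 peak lists on the mm10 assembly. Each replicate's list came from that replicate's filtered alignments and a control alignment of its own, so the lists of the replicates do not share a control. The pooled list came from the alignments of both replicates and both controls. The replicated list came from the pooled list and both replicate lists. The peak caller, its version, its thresholds and the aligner are not given in the sources used here. For each peak the authors gave a fold enrichment (a ratio of ChIP over control), a −log10 p-value, a −log10 q-value, a summit and a display score. The deposited score was not used for any result. The fold and the −log10 q-value, both the authors' values, served to describe, rank or filter peaks within a list, which includes comparing the fold between chromosomes of the replicated list. The deposited lists hold no read counts, so the depth of each sample is unknown here, and differences in depth between replicates could change how many peaks each list holds. The control alignments were not analysed here.

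Gene positions were taken from GENCODE mouse release M21, on GRCm38.p6, whose primary chromosomes are those of mm10. All 4 lists lie on chromosomes 1 to 19 and X, so 21755 protein-coding genes on these 20 chromosomes were used. A promoter was the 2000 bp window centred on the 5′ end of the gene, and it was called marked where peaks of the replicated list covered at least 500 bp of it. Peaks of a replicate were called shared where the overlap with a peak of the other replicate reached 50% of either peak. Domains were replicated peaks joined across gaps of at most 3 kb. Base pairs of peaks were assigned to promoters first, then exons, introns and intergenic sequence. CpG observed over expected and GC content were computed from the mm10 sequence, and a promoter was called CpG-rich at a CpG observed over expected of 0.6 or more.

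The design has 1 group, so no treatment was compared and no regrouping of samples was possible. Comparisons were made between gene lists, regions and the replicates. The 23 gene lists were fixed before the data were examined and were tested for marked promoters against all other protein-coding genes with a two-sided Fisher exact test and Benjamini-Hochberg adjustment over the 23. The facial list was tested in the same way against 7 lists of other lineages. Genes are not independent replicates, and p-values over genes measure how a list stands apart in these embryos. Overlaps, genomic distribution and CpG content were tested against 1000 circular shifts, in which all peaks of a chromosome move by 1 random step between 3 Mb and 100 kb from its end. These permutation tests were two-sided, and 0.001 is the smallest p they can give. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error over peaks or genes only. Errors are the SD over the values from each replicate's own list (n = 2).

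Genes named in the text followed a rule fixed in advance. For each list of 10 or more genes it took up to 4 marked members with the most covered base pairs in the window, with ties broken by coverage within 10 kb and then by symbol. It also took up to 2 unmarked members with the fewest. The genes of the 10 widest domains, those nearest the 5 peaks of highest fold, and counts per Hox cluster were added. Any other gene named was chosen after its values were seen.

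The calculations were tested on simulated data. Coverage in 200 windows after shifts differed from a direct count in 0 cases. On 100 sets of shifted peaks, 0.13% of the 2300 list tests were called. Lists of 25 random genes with 60% of members seeded as marked were recovered at 61.6% on average, and 100% of them were called. Both checks used shifted peaks, which mark few promoters (after circular shifts, 1.72 of the 39 Hox genes on average). They therefore do not measure error or power of the list tests at the 22.1% of promoters marked in the data. Peaks moved by a small random step, much shorter than the narrowest peak of replicate 1 (185 bp), were found shared in 100% of cases. The overlap rule fixed that outcome, so it checks the code only. Peaks moved at random along the chromosome were found shared in 2.60%. Alternatives covered the overlap rule, the coverage rule, the promoter definition, the peak list, each replicate left out, stricter q and fold limits, CpG-rich promoters, 1 gene per 100 kb, and circular shifts in place of the Fisher test. Alternatives on overlap used 100 shifts. Alternatives on distribution were first run with 100 and, after results had been seen, run again with the 1000 shifts of the main result, because the intron call at q of 0.01 or lower had been lost with 100 only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.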

Results

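H3K27me3 ChIP-seq peaks were examined in the facial prominence of mouse embryos at day 10.5, the tissue that gives rise to the upper and lower jaws and the midface. The group held 2 biological replicates, of 69 and 51 pooled embryos. Replicate 1 had 131169 peaks covering 82.5 Mb, and replicate 2 had 126411 peaks covering 74.6 Mb. The authors' pooled list held 174433 peaks, and their replicated list held 66830 peaks covering 85.0 Mb, or 3.23% of chromosomes 1 to 19 and X. Replicated peaks had a median width of 662 bp and a median fold over control, as given by the authors, of 3.17. Read totals are unknown, so no value below carries a measure of depth.

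The first comparison asked which promoters carried the mark. Peaks of the replicated list marked 4816 of 21755 protein-coding promoters (22.1%), and the lists of the replicates marked 4531 ± 38.2 (SD, n = 2). All 39 Hox genes, which set position along the body axis, were marked, as were all 30 transcription factors of brain and eye. Of the neuronal differentiation factors 29 of 30 were marked, of the trunk and limb mesoderm factors 23 of 25, of the endoderm organ factors 20 of 22, and of the heart factors 13 of 15. At the other end, 2 of 32 ribosomal protein genes and 2 of 30 housekeeping genes were marked. Of the 23 lists, 17 were marked more often than other genes and 1, the ribosomal protein genes, less often.

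**Figure D1:**
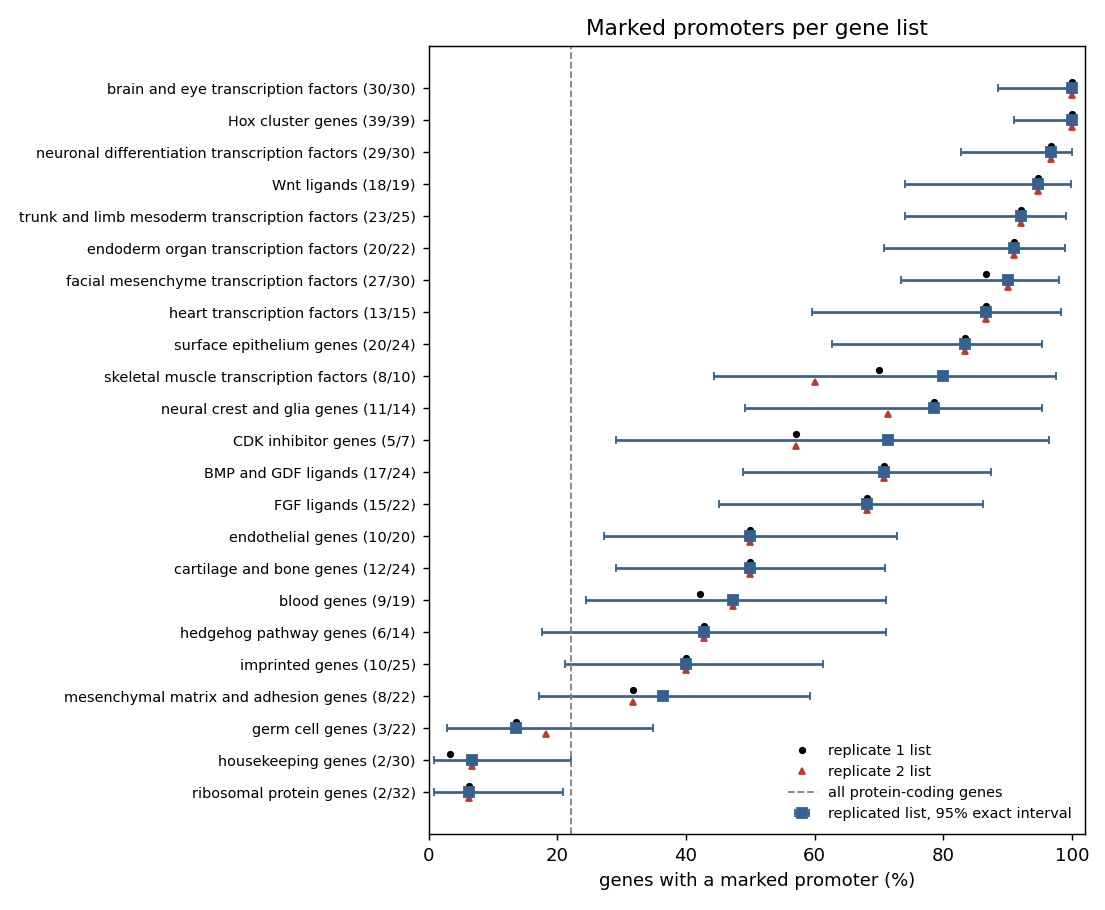
Percent of each list's genes with a marked promoter (x axis) for the 23 gene lists (y axis, marked over matched genes in parentheses); squares are the authors' replicated list with 95% exact intervals over genes, circles and triangles the lists of replicates 1 and 2, and the dashed line all protein-coding genes (22.1%). Hox and brain and eye factors sit at 100%, and ribosomal protein genes at 6.25%.

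Among lineage regulators, the promoter windows of Emx2, Gbx2, Gsx2 and Olig2, regulators of forebrain, midbrain and spinal cord progenitors, were covered over all 2000 bp in both replicates. The same held for Lhx1, Lmx1b, Neurod2 and Neurog2 among the neuronal factors, and for Cdx2, Mnx1, Foxa1 and Foxa2 among the endoderm factors. Tbx5 and Wt1, regulators of forelimb and kidney, were also covered over 2000 bp in both replicates, as were Uncx and the myogenic factor Myod1. Lbx1, Pax7 and Tcf21 completed the 4 leading members of the skeletal muscle list, of which 8 of 10 were marked. In the heart list, Nkx2-5, Tbx20, Hand1 and Tbx2 were covered over 2000 bp in the replicated list. Over the replicates Tbx2 had 1939 ± 49.5 bp (SD, n = 2). Unmarked members at 0 bp in the replicated list were Neurod4, Mef2c, Smyd1, Eya1, Hnf4a, Hnf4g, Msgn1 and Tbx6. The difference from other genes was 78.0 percentage points for the brain and eye list (Fisher exact test, adjusted p = 2.42e-19), 74.6 for the neuronal list (adjusted p = 1.73e-17) and 57.9 for the skeletal muscle list (adjusted p = 0.000295). With only CpG-rich promoters in the test, which left 4 genes of the skeletal muscle list, the difference was 27 points and was no longer called (Fisher exact test, adjusted p = 0.25).

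Ligands of signalling pathways were marked as groups. Of the Wnt ligands 18 of 19 were marked, led by Wnt10a, Wnt1, Wnt10b and Wnt6 at 2000 bp in both replicates. The exception was Wnt5a, a ligand needed for outgrowth of face and limb, with 350 bp in the replicated list and 263 ± 247 bp in the replicates (SD, n = 2). Within 10 kb either side of its 5′ end 7077 bp were covered, so the mark was present nearby. Of the BMP and GDF ligands 17 of 24 were marked, with Bmp4, Gdf10, Gdf7 and Bmp7 at 2000 bp, while Bmp10 and Bmp15 had 0 bp. Of the FGF ligands 15 of 22 were marked, led by Fgf16, Fgf3, Fgf11 and Fgf8; Fgf20 and Fgf7 had 0 bp. The differences were 72.7 points for Wnt (adjusted p = 7.85e-11), 48.7 for BMP and GDF (adjusted p = 1.12e-06) and 46.1 for FGF ligands (adjusted p = 1.04e-05), by Fisher's exact test. Of 14 hedgehog pathway genes 6 were marked, which did not pass the Fisher exact test (adjusted p = 0.107) but did with wider promoters (0.0317). The list also passed against circular shifts (adjusted permutation p = 0.00115). Circular shifts compare with random positions, so that pass does not set the list apart from other genes. In the replicated list the ligands Shh, Ihh and Dhh were each covered over 2000 bp, Hhip over 1811 bp, and Gli3 and Smo over 0 bp. Over the replicates Hhip had 1252 ± 78.5 bp (SD, n = 2).

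Markers of other cell types that the tissue could hold were also tested. Surface epithelium genes were marked in 20 of 24 cases, with Ovol1, Grhl3, Dsp and Pitx3 at 2000 bp and the basal keratins Krt14 and Krt5 at 0 bp. Neural crest and glia genes were marked in 11 of 14 cases, led by Foxd3, Phox2b, Ret and Sox10, with Fabp7 and Mpz at 0 bp. Endothelial genes were marked in 10 of 20 cases: Dll4, Flt1, Sox7 and Sox18 were covered over 2000 bp, and Cdh5 and Emcn had 0 bp. Cartilage and bone genes were marked in 12 of 24 cases, with Ihh, Comp, Acan and Sox6 at 2000 bp and Bglap and Col10a1 at 0 bp. Blood genes were marked in 9 of 19 cases, led by Tal1, Klf1, Gfi1b and Epor, with Gata1 and Gypa at 0 bp. Within 10 kb either side of the 5′ end, 5601 bp were covered at Mpz and 474 bp at Fabp7. The other unmarked genes named in this paragraph had 0 bp there too. CDK inhibitor genes were marked in 5 of 7 cases. Adjusted p-values (Fisher exact test) were 9.22e-10 for surface epithelium, 2.20e-05 for neural crest and glia, 0.00405 for cartilage and bone, 0.00866 for endothelial, 0.0107 for CDK inhibitor and 0.0294 for blood genes. The blood call ended with any overlap, with 1000 bp covered and with wider promoters, where the difference went from 25.3 points to between 18.6 and 20.4 (exact test, adjusted p from 0.075 to 0.103), and the endothelial call with any overlap, from 27.9 to 23.1 points (0.0529). The cartilage and bone difference was larger among CpG-rich promoters, at 43.7 against 27.9 points, but only 3 of its genes remained and it was not called (exact test, adjusted p = 0.162), and the CDK inhibitor call ended with 1 gene per 100 kb, from 49.3 to 40.1 points (0.0534).

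Genes of mesenchymal matrix and adhesion were marked in 8 of 22 cases (adjusted p = 0.128, Fisher exact test), and passed with wider promoters (0.0267) and the pooled list (0.0457). Against circular shifts, which compare with random positions and not with other genes, the list also passed (adjusted permutation p = 0.00115). Thy1, Lox and Fbn1 were covered over 2000 bp in the replicated list and Col1a1 over 1872 bp (1839 ± 17.0 bp over the replicates, SD, n = 2). Fibrillar collagen genes of the list went both ways. Besides Col1a1, Col1a2 (561 bp) and Col5a1 (627 bp) were marked in the replicated list, whereas Col3a1 and Col5a2 had 0 bp. Imprinted genes were marked in 10 of 25 matched cases of 27 listed (exact test, adjusted p = 0.0567), with Grb10, Igf2, Kcnq1 and Rasgrf1 leading and Igf2r and Impact at 0 bp. The list passed the test with either replicate alone, the pooled list, 1000 bp covered, a fold of 3 or more, and 1 gene per 100 kb (exact test, adjusted p from 0.0101 to 0.039). It also passed against circular shifts (adjusted permutation p = 0.00115), again a comparison with random positions only. Germ cell genes were marked in 3 of 22 cases (exact test, adjusted p = 0.446): Tdrd1, Nanos2 and Nanos3. The 2 marked ribosomal protein genes were Rpl3 and the X-linked Rps4x, and the list stood 15.9 percentage points below other genes (exact test, adjusted p = 0.0396). That call ended with the list of either replicate alone, where the difference was -14.7 and -14.5 points (exact test, adjusted p = 0.0575 and 0.0544), with a fold of 3 or more (-14.3 points, 0.054) and with 1000 bp covered (-11.4 points, 0.115), and the sign turned against circular shifts. The 2 marked housekeeping genes were the X-linked Pgk1, at 1505 ± 91.9 bp (SD, n = 2), and Actb, which had 0 bp in replicate 1 and 918 bp in replicate 2. The housekeeping list missed the threshold (exact test, adjusted p = 0.055) and passed it among autosomal genes (adjusted p = 0.0228), with wider promoters, any transcript start, the pooled list, a fold of 3 or more or 1 gene per 100 kb (0.00722 to 0.0362), and without replicate 2 (0.0181), but not without replicate 1 (0.0795). Against circular shifts its sign turned too, with 2 marked genes against 1.46 on average (permutation p = 0.645).

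The second comparison set a list of transcription factors of facial mesenchyme against lists named for other lineages. Whether members of those lists also act in the face was not tested, so this was a comparison of lists and not of face with other tissue. Of 30 transcription factors of facial mesenchyme, 27 were marked (90.0%; 88.3% ± 2.36 over the replicates, SD, n = 2). Hand2, Dlx6, Foxf1 and Pax9, which pattern the jaws or their derivatives, were covered over 2000 bp in the replicated list and over all 20 kb around the 5′ end. The 3 unmarked members were Prrx2, with 0 bp, Snai2, with 452 bp, and Sox9, with 466 bp. Within 10 kb either side of their 5′ ends, 1748, 1526 and 7401 bp were covered. Sox9 was chosen after its value was seen. The facial share was 10 points below that of the Hox list and that of the brain and eye list. It was 10 points above that of the skeletal muscle list. No difference from the 7 lists passed the Fisher exact test (adjusted p from 0.542 to 1). The Hox and brain and eye lists were at 100%, so neither could have stood further above, and the muscle list held 10 genes. The test therefore does not show that the lists were marked equally. By covered sequence within 10 kb either side, an alternative chosen after the data were seen, facial factors had a median of 18.0 kb. This was below the 20.0 kb of Hox genes (adjusted permutation p = 0.00014) and above the 6.67 kb of skeletal muscle factors (adjusted permutation p = 0.0123), and the other 5 differences did not pass. Hox genes are neighbours whose windows overlap, so they are not independent. The muscle list holds the neighbours Myf5 and Myf6, both with 3556 bp covered. The facial list holds Dlx1 beside Dlx2 and Dlx5 beside Dlx6. The permutation over genes treats them all as independent.

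The third comparison concerned broad domains. The mark covered 99.9% of the Hoxa cluster (chromosome 6, 52155590 to 52260880), 100% of Hoxc (chromosome 15, 102921103 to 103036852) and 99.6% of Hoxd (chromosome 2, 74668310 to 74765142). Hoxb (chromosome 11, 96194316 to 96368256) was covered over 88.2% (85.4% ± 0.366 over the replicates, SD, n = 2). Joined peaks made 21959 domains, of which 2685 were 10 kb or wider, 545 of them on X. Of the 10 widest, 9 lay on X. The widest (X, 99112811 to 99678262, 565 kb) held the 5′ ends of Efnb1, a gene needed for normal facial development, and Pja1. Others on X held Tsc22d3, Mid2 and Tex13b (379 kb), Rai2 (356 kb), Hsd17b10, Ribc1, Smc1a and Iqsec2 (272 kb), Nhsl2 and Rtl5 (264 kb), Zcchc13 and Slc16a2 (240 kb), and Ppef1, Rs1 and Gja6 (232 kb), and 2 held no protein-coding 5′ end. The Hoxc domain, at 264 kb, was the widest autosomal one, followed by Hoxb (190 kb), Hoxa with Evx1 (188 kb), the Rhcg region on chromosome 7 (136 kb) and Hoxd with Evx2 (130 kb). Joining across gaps of at most 1 kb gave 1771 domains of 10 kb or more, and the pooled list gave 4824.

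**Figure D2:**
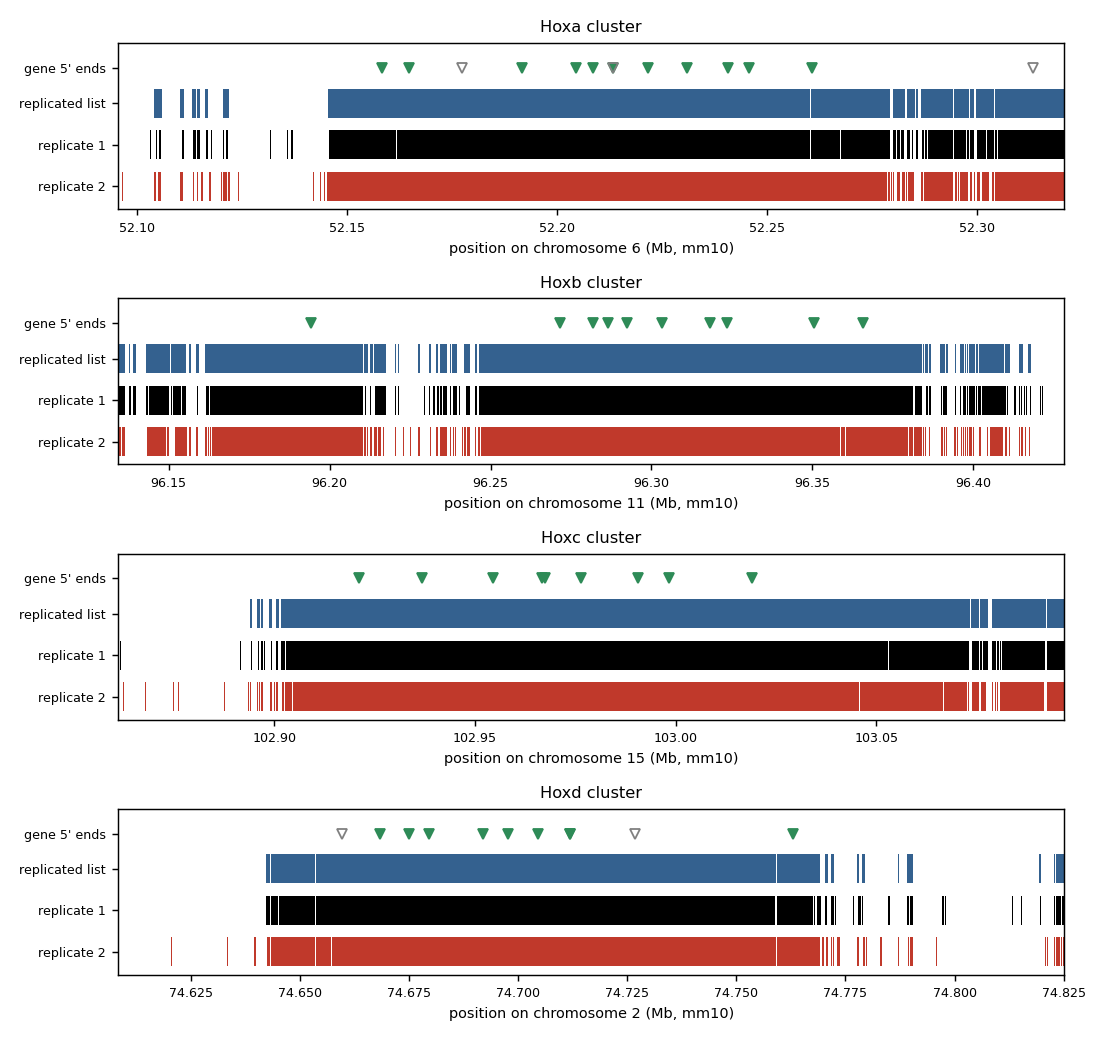
Peaks over the 4 Hox clusters on mm10 (x axes, position in Mb), drawn to scale for the authors' replicated list and the lists of replicates 1 and 2 (y axes); filled triangles mark the 5′ ends of Hox genes and open triangles those of other protein-coding genes. Coverage of the span of each cluster is 99.9% for Hoxa, 88.2% for Hoxb, 100% for Hoxc and 99.6% for Hoxd.

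The 5 peaks of highest fold lay in or near Rbfox3, Barhl1, Adra2c, Gsx1 and Neurog3. The highest, at 31.8, covered 118566034 to 118575468 on chromosome 11, with its summit inside Rbfox3, a gene of mature neurons; the nearest 5′ end was that of Engase, 93016 bp away. The next lay at Barhl1 on chromosome 2 (fold 28.2) and at Adra2c on chromosome 5 (28.1). A peak on chromosome 5 with a fold of 27.5 lay 33847 bp from the 5′ end of Gsx1, in no gene. The fifth, on chromosome 10, had its summit 2883 bp from the 5′ end of Neurog3 and inside Fam241b (fold 27.3).

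Promoters and exons were covered more than after shifts. Promoters took 9.01% of replicated peak sequence, against 1.60% on average after circular shifts, and exons 7.05% against 3.21% (permutation p = 0.001 for each, the smallest possible). Intergenic sequence took 45.7% against 60.3% (permutation p = 0.001). Introns took 38.2% against 34.9% (permutation p = 0.018), a call that ended without replicate 1 (37.3%, permutation p = 0.081) and turned with promoters of 2.5 kb either side (32.5%, permutation p = 0.298). The median CpG observed over expected of peaks was 0.192, against 0.152 after shifts (permutation p = 0.001). The difference lay on the autosomes, at 0.214 against 0.161 (permutation p = 0.001), and was not called on X, at 0.129 against 0.124 (permutation p = 0.115). The median GC content was 49.2% against 41.1%, with 50.6% against 41.9% on the autosomes and 42.9% against 38.9% on X (permutation p = 0.001 for each). CpG-rich promoters were marked in 1710 of 7444 cases (23%) and CpG-poor ones in 3106 of 14311 (21.7%). When promoters were ranked by CpG observed over expected and parted into 10 equal groups, the share marked was 1.93% in group 1, 41.8% in group 5 (0.361 to 0.478) and 16.0% in group 10.

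**Figure D3:**
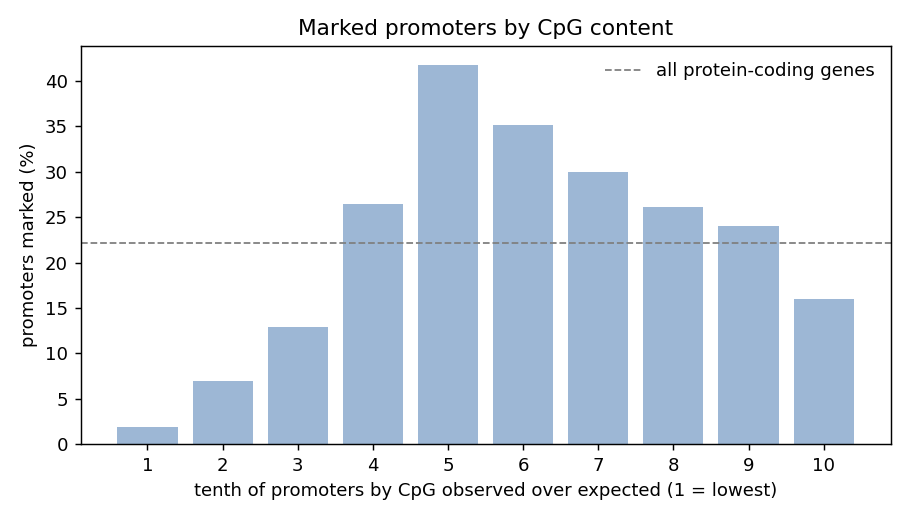
Percent of promoters marked (y axis) in 10 equal groups of protein-coding promoters ranked by CpG observed over expected (x axis, 1 is lowest); bars are the authors' replicated list and the dashed line all genes (22.1%). The share is highest, 41.8%, in group 5 and 16.0% in group 10.

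The X chromosome stood apart from the autosomes. Peaks covered 10.7% of X, against an autosomal median of 2.75% and a highest autosome of 4.93% (chromosome 11). The ratio of X to the autosomal median was 3.87 in the replicated list and 3.54 ± 0.344 over the lists of the replicates (SD, n = 2). Promoters on X were marked in 374 of 948 cases (39.5%), against 21.3% on autosomes. The median of the authors' fold was 3.39 on X, above the highest autosome at 3.17, whereas the 99th percentile was 6.90 on X and 13.9 at the autosomal median. With male and female embryos pooled in both samples, no comparison of sexes was possible.

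**Figure D4:**
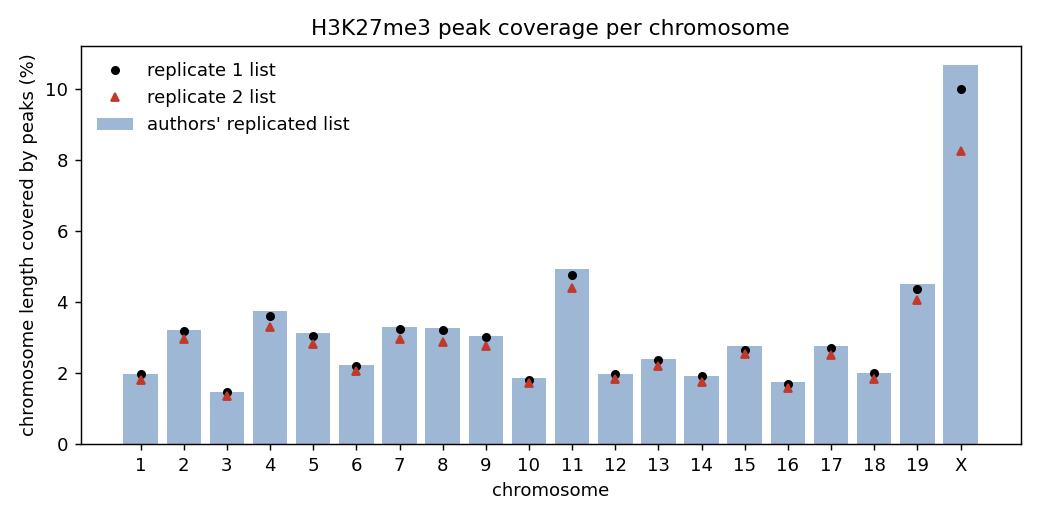
Percent of each chromosome's length covered by peaks (y axis) for chromosomes 1 to 19 and X (x axis); bars are the authors' replicated list, circles and triangles the lists of replicates 1 and 2. X is covered over 10.7%, above chromosome 11 at 4.93%.

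The last comparison was between the replicates. Of the peaks of replicate 1, 46.8% were shared with replicate 2 (exact 95% interval 46.5 to 47.1%), against 5.12% on average after shifts (permutation p = 0.001, the smallest possible). The share depended on the overlap rule: it was 54.8% with an overlap of at least 1 bp and 26.6% where 50% of both peaks had to overlap. Of the peaks of replicate 2, 53.0% were shared. For replicate 1, sharing was 59.9% on X, against 10.9% on average and at most 41.7% after shifts, and 43.4% on autosomes, against 3.60% on average; the difference between X and autosomes was not tested. The 10% of replicate 1 peaks with the highest fold were shared in 98.0% of cases and the 10% with the lowest in 26.0%. Their median widths were 1795 and 232 bp, and no shifts were run for these groups. Fold and width therefore cannot be told apart here. Covered sequence common to both lists was 50.9% of that in either. The replicated list kept 38.3% of pooled peaks, with a median width of 662 bp against 236 bp for those not kept. All 54534 pooled peaks shared with both replicates were kept, and they made up 81.6% of the replicated list.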

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

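The autosomal, repeat and 10 kb settings, and the fold limit for X, were chosen after the data were seen. Of 299 list values under 13 settings, 268 stayed on the same side of the threshold, and 12 of the 17 higher lists did so in every setting. Lists not called in the main test were counted by call alone, and some of their values changed sign. The number of higher lists ranged from 15 to 20. The 20 came from circular shifts, 1 of the 13 settings, which compare with random positions and not with other genes. Of 77 facial list values, 75 stayed on the same side, and of 595 coverage values of single named genes, 40 moved. Of the 4816 marked promoters, 91.3% were also marked by the list of replicate 1 alone and 92.0% by that of replicate 2 alone. Depth is unknown, so its share in these differences could not be measured. No paired analysis was possible because the design holds 1 group.

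Differences from other genes, in percentage points, changed call as follows. With any overlap, blood genes stood at 20.4 and endothelial genes at 23.1, and neither was called. With 1000 bp covered, blood genes (19.3) and ribosomal protein genes (-11.4) were no longer called, and imprinted genes (22.4) were. With promoters of 2.5 kb either side, blood genes (18.6) lost the call, and mesenchymal matrix (22.0), hedgehog (26.5) and housekeeping genes (-20.2) gained it. With any transcript start, housekeeping genes (-19.0) gained it. The pooled list gained matrix (21.3), imprinted (19.8) and housekeeping genes (-17.5). A fold of 3 or more gained imprinted (19.5) and housekeeping genes (-17.2) and lost ribosomal protein genes (-14.3). Autosomal genes alone gained housekeeping genes (-17.8). CpG-rich promoters lost skeletal muscle (27) and cartilage and bone genes (43.7), where fewer genes were tested. With 1 gene per 100 kb, which also tests fewer genes, CDK inhibitors (40.1) were lost and imprinted (23.5) and housekeeping genes (-19.9) gained. Without 1 replicate, imprinted genes ranged from 19.1 to 19.3 and were called both times, ribosomal protein genes from -14.7 to -14.5 and were called neither time, and housekeeping genes from -17.4, called without replicate 2, to -14.3, not called without replicate 1. Against circular shifts, which compare with random positions and not with other genes, matrix (32.8), hedgehog (38.9) and imprinted genes (35.4) gained the call. Ribosomal protein genes turned to 1.35 above. Housekeeping genes (2 marked against 1.46 on average after shifts) and germ cell genes (3 against 0.918) also turned and were not called. Apart from these differences of construction, the cause was not tested.

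Shared peaks of replicate 1 ranged from 26.6%, where 50% of both peaks had to overlap, to 54.8% with at least 1 bp. By covered sequence within 10 kb, 2 of the 7 facial comparisons passed, with differences of medians of -2.04 kb against Hox and 11.3 kb against skeletal muscle. With q of 0.01 or lower, 47.2% of pooled peaks were kept. The intron share was 32.5% with wider promoters, not called, and ranged from 37.3%, not called without replicate 1, to 38.7%, called without replicate 2. Domains of 10 kb or more numbered 1771 with 1 kb gaps and 4824 from the pooled list. The ratio of X to the autosomal median ranged from 3.30 to 3.78 without 1 replicate and was 4.57 outside repeats. The cause of these was not tested.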

Other observations

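The gene families, the gene types, the length-matched X genes and the q limit on replicate 1 alone were chosen for testing after results had been seen. The q limit on the shared share was planned, but its bound was set after results had been seen. Genes were grouped by the letters that open their symbol, and 161 groups of at least 15 genes were tested (Fisher exact test, Benjamini-Hochberg over the 161), of which 21 were marked more often and 30 less often than other genes. The Syt genes, synaptotagmins that act as calcium sensors of vesicle release, were marked in 13 of 17 cases (exact test, adjusted p = 5.80e-05). Genes with symbols opening in Col, mostly collagens, were marked in 30 of 45 cases (exact test, adjusted p = 6.46e-09), with Col3a1 and Col5a2 among those at 0 bp. Sox genes were marked in 12 of 19 cases, Sema genes, which encode axon guidance signals, in 12 of 20, and Kcnj potassium channel genes in 9 of 15 (exact test, adjusted p = 0.00142, 0.00229 and 0.00975).

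Other families were marked less often than other genes. Of 1135 olfactory receptor (Olfr) genes 3 were marked, of 331 vomeronasal receptor (Vmn) genes 0, of 394 Zfp genes 26 and of 67 Hist genes 1 (exact test, adjusted p = 1.25e-118, 6.89e-35, 3.00e-15 and 4.50e-05). The 22 Pcdhb genes, a protocadherin cluster on 1 chromosome, and the 34 Rhox genes, a cluster on X, had 0 marked members (exact test, adjusted p = 0.0298 and 0.00229). Genes of such clusters are neighbours and not independent. Among other gene types, 19.0% of 2958 antisense, 12.8% of 5305 lincRNA and 3.69% of 9849 processed pseudogene 5′ ends were marked.

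X was covered more than every autosome. Were calls with a fold below 3 the reason, the ratio to the autosomal median would fall without them. With a fold of 3 or more it was 4.10. That limit lay below the median fold on X (3.39), and the 99th percentile was lower on X (6.90) than at the autosomal median (13.9). Higher limits were not run, so a part for calls of modest fold stays open. Were repeats the reason, the ratio would fall outside them, yet it was 4.57. The hypothesis of an inactive X in the female embryos was put to 11 genes listed in advance as escaping inactivation, after the edge of a wide domain near Kdm5c had been noticed, and it cannot be told apart from others here. The median covered share of their bodies minus that of other X genes was 0 percentage points (permutation p = 1), which met the bound set beforehand against the hypothesis, but both medians lay at 0%, so no list could have fallen lower. For that reason, seen only with the result, the test is taken to decide nothing. Of the 11 genes, 6 (54.5%) had 0 bp, against 486 of 941 other X genes (51.6%) and 70 of 190 matched in length; of 10000 random lists matched in length, 15.3% had a median as low and 16.1% as many genes at 0 bp.

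The replicates shared 46.8% of the peaks of replicate 1, and 26.6% where the overlap had to reach 50% of both peaks. A candidate explanation is that broad domains were broken up at different places: 76.4% of unshared peaks lay within 3 kb of a peak of the other replicate, 4.93 times the 15.5% after shifts, although peaks gathered in the same regions would also raise this ratio. Peaks of lower fold or higher q were shared less often, but weak calls cannot be told apart as the reason for the share of 46.8%. Limiting both lists to q of 0.01 or lower raised the shared share by 0.596 points, which was under the bound set against weak calls, but that limit also removes partners. With the limit on replicate 1 alone, 54.0% of peaks passing it and 22.9% of the others were shared. The top and bottom 10% by fold differed by 72.0 points, but also in median width (1795 and 232 bp), so the gap cannot be laid to fold alone.

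The share of marked facial mesenchyme factors differed from that of no other lineage list by the exact test. With the Hox and brain and eye lists at 100%, no larger gap above the facial share was possible, so equal marking is not shown. A loose coverage rule is argued against only as far as 1000 bp, where the facial share minus that of the other lists joined was -3.53 points. Every marked facial factor had at least 1448 bp in the replicated list, so the facial share stayed at 90%. Limits above 1000 bp were not run. Saturation of the promoter window cannot be told apart: the facial median within 10 kb either side differed by -1096 bp from that of the others (permutation p = 0.509), which neither meets nor excludes it. List by list, facial coverage within 10 kb was lower than that of Hox genes and higher than that of skeletal muscle factors (permutation, adjusted p = 0.00014 and 0.0123), and the other 5 comparisons did not pass. The facial, Hox and muscle lists each hold neighbouring genes, which the permutation treats as independent. A mixture of cells with and without the mark in dissected tissue was not tested, since peak lists hold no signal per cell.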
